A study of Mus musculus with 4 samples.

How the data were processed

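Single-cell RNA sequencing counts of 4 samples of sorted mouse AT2 cells were analysed, 2 KRAS wild type and 2 KRAS mutant. Per the labels' protocols, lungs were digested with dispase, cells were sorted, cDNA was made on a Fluidigm C1 system and libraries were made with a Nextera XT kit. The deposited table holds read counts per gene and well, as whole numbers. Per the submitters' processing notes, CASAVA 1.8, FastQC, STAR, featureCounts and the GRCm38 build were used, with no order or settings attached. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of close paralogs, pseudogenes, and overlapping or antisense genes are uncertain. The table has 53715 features, of which 53620 matched a symbol by Ensembl identifier in the GENCODE M21 annotation of GRCm38, which also gave coordinates. Spike-ins held 0.723% of all reads and stayed out of library sizes and tests. The 40 columns of unassigned reads were not used.

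Wells with at least 500 genes and at most 30% mitochondrial reads were kept, 1351 of 1600. No doublet caller was run and no doublets were removed. Counts were scaled to 10000 per well, log-transformed and clustered with scanpy 1.11.5 by the Leiden method as implemented in igraph. The clustering used genes seen in at least 10 wells, 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 0.5. A cluster was named only from fixed markers: it needed at least 2 markers of 1 type, and more than of any other type, among its 10 leading genes by fold. Deep wells, with at least 50000 reads, were clustered again by the same steps. Of these 642 wells, 489 lay in the 2 clusters whose Sftpc level was above 50% of the highest. At a resolution of 0.25, 535 deep wells formed 1 AT2-like cluster. Shares were compared by a two-sided exact permutation test, and intervals are exact Clopper-Pearson 95% intervals. Thinning to 50000 reads left out 297 and 170 wild type and 199 and 43 mutant wells.

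Counts were summed over the passing wells of each sample, since wells are not replicates. edgeR 4.0.16 in R 4.3.3 was run with its low-count filter, TMM scaling and the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 difference over the square root of F, and CPM are counts scaled to library size with TMM factors. The 32 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and medians of lists are on that scale. Of these, 30 had at least 3 tested genes. The basal and erythroid lists did not. An estimated correlation and fry were run beside it. Intervals of list medians came from resampling wells within a run 500 times, with 2 CPM added before the logarithm, so these medians are not on the scale of the others. A fold against a group with no read is a bound against 3 reads over that group. The 2 samples of a genotype differed far beyond the sampling noise of reads (chi-square per degree of freedom 545 in wild type and 515 in mutant), and each counted as 1 sample. Different wells and cell mixes can give such a spread, so it does not show that the samples are independent.

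The labels do not say what a run number stands for. In the column names wild type takes chip columns 1 to 10 and mutant chip columns 11 to 20 under each run number, and on that ground the numbers were taken to pair the samples. The differences between run 1 and run 2 in the 2 genotypes correlated across genes (r = 0.471), which are not independent replicates. The reported fit has no run term, and a replicate block was an alternative.

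Tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined. Where fewer than 5 genes pass in a direction, the rule names the 12 with the smallest unadjusted p, with the rule's minimum mean of 10 CPM in 1 group kept here, and up to 4 members of each list with the smallest unadjusted p, and Kras. Genes without a proper name were counted but not named. Sftpc, Chil3, Ptprc, Igha, Usp18, Isg15 and Msln were named after their values had been seen. The tests were run on simulated counts first, in 5 simulations of 17651 genes. Of 50 lists of 25 genes shifted 2-fold, camera called 19 with the preset correlation and 0 with an estimated one, and it called 0 of 50 unchanged lists. Simulated from the surfactant-high wells, it called 32 of 50 shifted and 1 of 50 unchanged lists with the preset correlation, and 0 of 50 shifted lists with an estimated one. The simulated genes were drawn independently, so these counts do not show how the preset value fares for lists whose members move together.

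Alternatives were other scalings, no low-count filter, DESeq2 1.42.0, a replicate block, leaving out each sample, other filters on wells, AT2-like clusters only, thinned wells, means of wells tested with limma, and other clusterings. Leaving out a sample leaves 1 in its group, which is then assumed to vary like the other group. Sets of deep wells, surfactant-high wells and each of their clusters, and the block within AT2-like clusters, were added after the data had been seen.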

Results

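Alveolar type 2 (AT2) cells, the surfactant-producing epithelial cells of the lung alveolus, were profiled by single-cell RNA sequencing 4 weeks after mice were infected with an adenovirus carrying Cre recombinase. Mice with a Cre-dependent oncogenic Kras allele (KRAS mutant) were compared with littermates without it (KRAS wild type), to look for early changes in lung tumour formation. Each genotype had 2 samples, named run 1 and run 2, and each sample filled 400 wells of a microfluidic chip. The sort took cells negative for the endothelial marker CD31 and the leukocyte marker CD45, intermediate for the epithelial marker EpCAM and positive for MHC class II. The reporter eYFP is not named among the sort markers. Nothing in the labels says that the runs came from separate animals, so p-values may not cover the spread between animals. Those of edgeR measure the spread between these samples, which may be technical, and those of camera rest also on the spread across genes. The mutant runs differed in sex markers, as given under other observations.

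Wild type runs 1 and 2 held 40905448 and 44581717 reads over all wells, and mutant runs 1 and 2 held 58682880 and 37224823. After wells with few genes or many mitochondrial reads were left out, 355 and 367 wild type wells and 359 and 270 mutant wells passed. Their median depth was 9512 and 66385 reads in the wild type runs, and 28214 and 131206 reads in the mutant runs. The deepest 10% of wells held 81.8% of the reads of wild type run 1, 32.3% of wild type run 2, 48.2% of mutant run 1 and 21% of mutant run 2. Intervals of shares given here cover the counting of wells, and intervals of list medians the spread between wells of a run. Floors cover the counting of reads, which without molecular identifiers are not independent molecules. None of them covers the spread between samples.

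**Figure D1:**
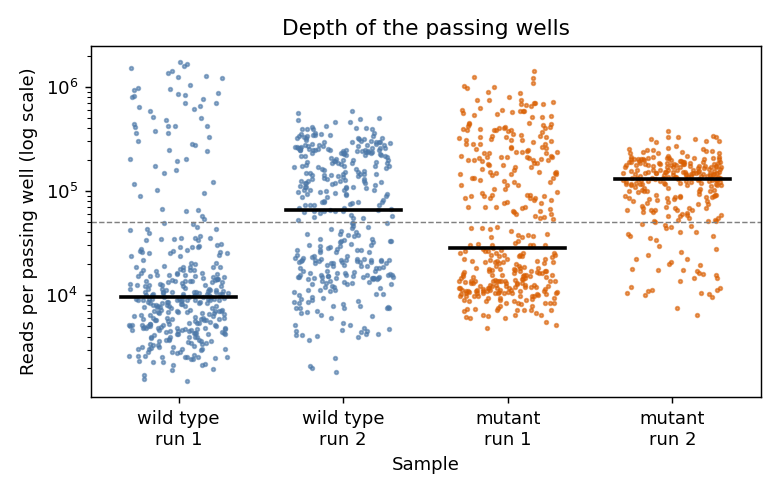
Reads per passing well on a log axis for the 4 samples, with 1 point per well, the sample median as a black bar and 50000 reads as a dashed line. The medians lie at 9512 and 66385 reads in the wild type runs and at 28214 and 131206 reads in the mutant runs.

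The cell types that the sort had delivered were examined first. Surfactant transcripts were abundant in all 4 samples, and run 1 of both genotypes also carried transcripts of leukocytes and airway cells. Sftpc, the surfactant protein C gene of AT2 cells, stood at 160155 and 263010 CPM in wild type runs and 120160 and 263735 CPM in mutant runs. Chil3, an alveolar macrophage gene, stood at 734 CPM in wild type run 1 and 1180 CPM in mutant run 1, against 0 and 4.29 CPM in run 2 of each genotype. Ptprc, which encodes CD45, stood at 163 and 238 CPM in run 1 of wild type and mutant, against 0.0253 and 4.82 CPM in run 2. The airway secretoglobin gene Scgb1a1 stood at 5054 and 1058 CPM in wild type runs and 30196 and 494 CPM in mutant runs, and the immunoglobulin light chain gene Igkc at 6096 and 0 CPM in wild type runs and 489 and 85 CPM in mutant runs.

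Wells with at least 50000 reads, here called deep wells, were clustered apart from the rest, a choice made after the depths had been seen. They numbered 58 and 197 in the wild type runs and 160 and 227 in the mutant runs. Cluster 1 was macrophage-like, led by Ctss, Chil3, Ccl5, Ccl6 and Tyrobp, with the immunoglobulin gene Igha also among its leading genes. It held 44.8% of the deep wells of wild type run 1 (95% exact interval 31.7 to 58.5) and 45% of those of mutant run 1 (37.1 to 53.1). In run 2 it held 0 of 197 wild type wells, which allows a share of up to 1.86% by the same interval, and 0.441% of mutant wells. The like shares of run 1 need not mean the same cells. With passing wells clustered at a resolution of 1.0, a macrophage-like cluster held 4 wild type and 48 mutant wells of run 1. A T and NK cell-like cluster held 1 and 16 of them. Cluster 3 was AT2-like, with Sftpb, Slc34a2, Cxcl15, S100g and Hc among its leading genes. Cluster 2 had 2230 Sftpc reads per 10000 against 2330 in cluster 3, but was led by Ly6i, the keratin genes Krt7, Krt18 and Krt8, Clu and the alveolar type 1 (AT1) gene Ager, and stayed unnamed. Cluster 5 was club-like, with Scgb1a1, Cyp2f2 and Scgb3a2 among its leading genes, and cluster 4 stayed unnamed. Clusters 2 and 3 together, the surfactant-high wells, made up 37.9% and 92.9% of the deep wells of the wild type runs, and 41.9% and 95.6% of those of the mutant runs. Cluster 2 held 32.2% ± 33.4 of wild type and 27% ± 16.1 of mutant deep wells (SD, n = 2; exact permutation test, two-sided p = 1). Among all passing wells, the AT2-like cluster held 34.8% ± 46.4 of wild type and 51% ± 45.3 of mutant wells (SD, n = 2; exact permutation test, two-sided p = 0.667). By run, the AT2-like share was 1.97% in wild type and 18.9% in mutant wells of run 1, and 67.6% and 83% in run 2, so the SDs mostly reflect the runs, which this test does not pair. With 2 samples against 2 the smallest p of this test is 0.333, so no share could pass 0.05, and the gap in depth between runs can set these shares. Passing wells of wild type run 1 clustered by chip column: of its 11 clusters with at least 20 wells, 9 held wells of 1 column only (adjusted Rand index 0.819), which leaves the low AT2-like share of that run uncertain.

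**Figure D2:**
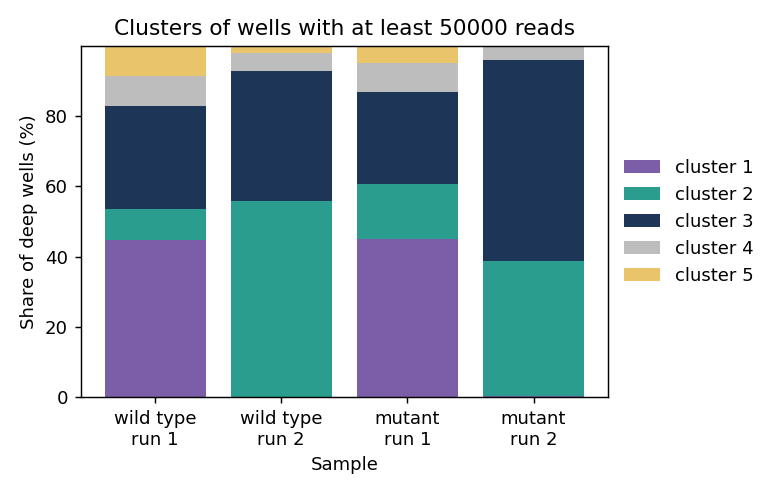
Share of deep wells (percent) in each of 5 clusters for the 4 samples, stacked from 0. Cluster 1, led by leukocyte genes, held 44.8% and 45% in run 1 of wild type and mutant, and 0% and 0.441% in run 2.

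Kras (ENSMUSG00000030265.14, chromosome 6 from 145216699 to 145250239 on GRCm38) stood at 61.1 ± 25.8 CPM in wild type and 60.4 ± 1.74 CPM in mutant samples (SD, n = 2). The log2 difference was -0.02 with a standard error of 0.45 (edgeR quasi-likelihood test, adjusted p = 0.9998). The introduced allele differs by a point mutation, so the level of Kras does not check the genotype labels.

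The comparison of KRAS mutant with wild type samples asked which genes and pathways had changed early. Genes of the type I interferon response and of cholesterol synthesis were lower as lists in mutant samples, and genes of the G2 and M phases of the cell cycle were higher. Of the 42 interferon genes, 38 were lower in mutant samples, and in 22 both mutant runs lay below both wild type runs, at a median log2 difference of -0.82 (camera, adjusted p = 5.7e-08; adjusted p = 0.884 with an estimated correlation). That difference was -0.94 in run 1 and -0.72 in run 2. With an estimated correlation between genes none of the 30 lists passed.

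No single gene passed. edgeR called 0 of 17651 genes, with 415 at an unadjusted p under 0.05, 263 higher and 152 lower in mutant samples. DESeq2 called 67 genes on the same sums, 46 higher and 21 lower, and limma on the mean of the wells called 0, with 276 at an unadjusted p under 0.05. Without mutant replicate 1 edgeR called 50 genes, 5 higher and 45 lower, and without mutant replicate 2 it called 4, all higher. The excess of higher genes at an unadjusted p under 0.05 did not hold in every fit. There were 411 higher and 426 lower with DESeq2, and 410 and 453 in edgeR with no low-count filter. The balance also turned to lower genes without mutant replicate 1. It stayed with the replicate block, at 380 higher and 288 lower, and without each of the other samples. Both mutant runs lay above both wild type runs in 2823 genes and below them in 2197, together 28.4% of genes, where 4 exchangeable samples would give 33.3% and a run effect shared by the genotypes would lower that figure. In simulated data of this size edgeR called 0.8% of genes changed 4-fold and 19% of genes changed 16-fold, so moderate changes of single genes were not detectable.

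Among the 12 named genes with the smallest unadjusted p on the higher side, Cenpf, a kinetochore gene, stood at 0.748 ± 0.16 CPM in wild type and 14.2 ± 6.83 CPM in mutant samples (SD, n = 2). Smc4, a condensin gene, stood at 30.1 ± 2.76 and 87.5 ± 9.81 CPM. Cdkn3, a cell cycle phosphatase gene, had no read in wild type and 7.77 and 15.4 CPM in the mutant runs, at least 286-fold higher against 3 reads over the wild type group. Retnla, a resistin-like secreted factor, stood at 62.8 ± 48.3 and 345 ± 13.4 CPM, and the metallothionein gene Mt2 at 8.06 ± 6.74 and 58.7 ± 7.83 CPM. The chemokine gene Ccl20 stood at 0 and 0.253 CPM in wild type runs and 386 and 33.3 CPM in mutant runs. Meg3, a long noncoding RNA, had a log2 difference of 4.35, St6galnac3 of 3.53, Dgkh of 3.35 and Rgs19 of 2.07, while Cib1 stood at 32.3 ± 10.2 against 113 ± 24 CPM. Lbhd2 stood at 0.0244 and 0 CPM in wild type runs and 123 and 8.65 CPM in mutant runs. With passing wells clustered at a resolution of 1.0, 1 unnamed cluster of 55 wells had Ccl20, Lbhd2, Msln and the club marker Scgb3a1 among its leading genes. It held 5 and 0 wells of the wild type runs and 50 and 0 of the mutant runs.

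On the lower side, Ldlr, the receptor for low-density lipoprotein, stood at 178 ± 18.2 CPM in wild type and 66.5 ± 3.42 CPM in mutant samples (SD, n = 2). The interferon-induced genes Oasl2 and Ifi27l2a stood at 153 ± 8.09 against 59.7 ± 5.33 CPM and at 1009 ± 874 against 151 ± 40.8 CPM, and Ddx60, an antiviral helicase gene, at 33 ± 0.547 against 3.52 ± 2.12 CPM. Cygb, which encodes cytoglobin, stood at 21.8 ± 0.636 against 1.47 ± 0.226 CPM and Prkar1b, a regulatory subunit gene of protein kinase A, at 27.3 ± 8.21 against 1.8 ± 0.453 CPM. Itln1, an intelectin gene, had 31.2 and 0.962 CPM in the wild type runs and no read in mutant samples, at least 486-fold lower against 3 reads over the mutant group. C3ar1, the complement C3a receptor gene, had a log2 difference of -6.18, mt-Ta of -2.02, Mast4 of -1.91, Fbxo31 of -1.86 and Fnip2 of -1.82. Each of these 24 genes had an adjusted p of 0.9998 in edgeR's quasi-likelihood test.

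In the type I interferon list, Stat2, a signal transducer of the interferon receptor, stood at 77.5 ± 32.5 CPM in wild type and 25 ± 5.03 CPM in mutant samples, and Ddx58, which encodes the RNA sensor RIG-I, at 65.4 ± 9.13 against 24.3 ± 3.12 CPM (SD, n = 2). No member of any list passed over all genes, and none passed adjusted over the list alone, where the smallest adjusted p of the interferon list was 0.184 in edgeR's test. With fry, which tests whether a list moves one way on balance, no list passed either, with an adjusted p of 0.277 for the interferon list and a smallest one of 0.135, for RAS MAPK output and glycolysis.

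Of 20 cholesterol synthesis genes, 19 were lower in mutant samples, 13 of them with both mutant runs below both wild type runs, at a median log2 difference of -0.73 (camera, adjusted p = 0.000176; adjusted p = 0.884 with an estimated correlation). Beside Ldlr, the lanosterol synthase gene Lss stood at 47.6 ± 13.4 against 14.2 ± 4.12 CPM, and Insig1, a sterol-sensing regulator, at 63 ± 18.6 against 31.7 ± 2.12 CPM (SD, n = 2). The median of the list was -0.30 in run 1 and -1.08 in run 2. The list did not pass without wild type replicate 2 (camera, adjusted p = 0.0778). Fatty acid synthesis genes did not pass, with 12 of 18 lower (camera, adjusted p = 0.194).

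Of 25 G2 and M phase genes, 23 were higher in mutant samples, 17 of them with both mutant runs above both wild type runs (camera, adjusted p = 3.1e-09; adjusted p = 0.884 with an estimated correlation). The median log2 difference was 2.88, and 1.61 over edgeR's fitted values. Ccnb1, the cyclin B1 gene, stood at 0.0868 ± 0.0154 CPM in wild type and 5.22 ± 0.798 CPM in mutant samples, and Birc5, which encodes survivin, at 2.02 ± 2.71 against 28.1 ± 9.74 CPM (SD, n = 2). S phase genes were higher in 14 of 23 members at a median of 0.65 (camera, adjusted p = 0.0376, and 0.884 with an estimated correlation), among them Uhrf1 at 0.0244 ± 0.0345 against 8.47 ± 5.17 CPM. In only 5 of the 23 did both mutant runs lie above both wild type runs. The S phase list passed in only 8 of the 14 alternatives fixed beforehand, with medians from -0.17 to 3.28. Few wells carried the G2 and M phase reads: 5 wells held 75.2% of them in mutant run 1 and 78.2% in mutant run 2, against 71.1% and 28.5% in the wild type runs. Of those 5 wells, 0 were surfactant-high in mutant run 1 and 4 in mutant run 2.

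RAS MAPK output genes, which report signalling downstream of KRAS, were higher in 18 of 25 members at a median log2 difference of 0.48 (camera, adjusted p = 0.0371; adjusted p = 0.884 with an estimated correlation). Etv4, a transcription factor gene induced by this pathway, had no read in wild type and 5.12 and 4.1 CPM in the mutant runs, at least 133-fold higher against 3 reads over the wild type group. Ccnd1, the cyclin D1 gene, stood at 45.6 ± 14.6 against 86.4 ± 31.4 CPM (SD, n = 2). Genes of the transitional alveolar state between AT2 and AT1 cells were higher in 15 of 18 members at a median of 0.97 (camera, adjusted p = 0.0371; adjusted p = 0.884 with an estimated correlation), with Krt19 at 52.3 ± 3.72 against 98.9 ± 17.1 CPM and Ccn2 at 1.31 ± 0.564 against 11.3 ± 5.79 CPM. AT1 markers were higher in 15 of 16 members at a median of 0.86 (camera, adjusted p = 0.0107, and 0.884 with an estimated correlation), with Pdpn at 26.7 ± 11 against 90.1 ± 65.3 CPM. Both mutant runs lay above both wild type runs in 6 of 25 RAS MAPK output, 3 of 18 transitional and 9 of 16 AT1 members. The same held for 2823 of all 17651 genes, a share much like that of the transitional list. Each of these 3 lists lost its call without wild type replicate 1 and without mutant replicate 2, at adjusted p of 0.211 and 0.744 for RAS MAPK output. AT2 identity genes did not pass, with 17 of 23 lower (camera, adjusted p = 0.194).

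Markers of other cell types differed beside these lists. Ciliated cell markers were lower in mutant samples in 13 of 13 members at a median log2 difference of -2.24 (camera, adjusted p = 0.000751), and B cell markers were higher in 9 of 12 at a median of 1.85 (camera, adjusted p = 0.0331). Both had an adjusted p = 0.884 with an estimated correlation. Both mutant runs lay below both wild type runs in only 1 ciliated marker, and above them in only 3 B cell markers. A ciliated-like cluster of 36 passing wells held 7 and 6 wells of the wild type runs and 23 and 0 of the mutant runs. In run 1 its wells thus went against the direction of the ciliated list. The B cell median was 0.67 over edgeR's fitted values and -1.90 without wild type replicate 2. Ms4a1, which encodes the B cell antigen CD20, stood at 0.293 ± 0.414 against 24.8 ± 8.11 CPM (SD, n = 2), while Igkc was lower in mutant run 1 than in wild type run 1, as given above. Markers of macrophages (camera, adjusted p = 0.785), dendritic cells (0.785), T and NK cells (0.762), neutrophils (0.194), club cells (0.937), endothelium (0.937), mesenchyme (0.762) and mesothelium (0.168) did not pass. Nor did MHC class I presentation (camera, adjusted p = 0.168), MHC class II presentation (0.618), interferon sensing and receptors (0.762), immune checkpoint ligands (0.721), NF-kB targets and chemokines (0.721), glycolysis (0.532), mitochondrial ATP synthesis (0.618), the unfolded protein response (0.937), p53 and senescence (0.785), dissociation genes (0.193) and early tumour dedifferentiation (0.328). The median or the mean of a list differed in sign from camera's direction for macrophage, dendritic cell, club, endothelial, interferon sensing, MHC class II, NF-kB and unfolded protein response genes. Mesenchymal markers had a median log2 difference of 1.08 but -0.61 over edgeR's fitted values.

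**Figure D3:**
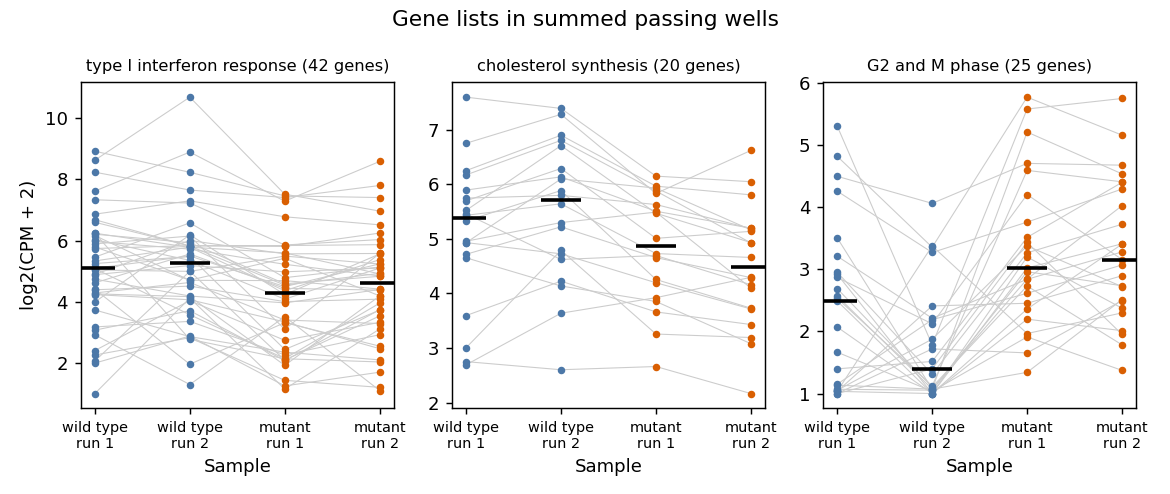
Values of the type I interferon response, cholesterol synthesis and G2 and M phase lists as log2(CPM + 2) in the 4 samples, with 1 point and 1 grey line per gene and the list median as a black bar. The interferon list has 42 genes, the cholesterol list 20 and the G2 and M phase list 25.

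Since other cells were present in run 1, the comparison was repeated on the surfactant-high deep wells alone, a set chosen after the data had been seen. It held 22 and 183 wild type wells and 67 and 217 mutant wells. Airway transcripts remained in run 1 of this set. Scgb1a1 stood there at 10584 and 445 CPM in wild type runs and 25841 and 442 CPM in mutant runs. The type I interferon response was lower there in 32 of 41 members at a median log2 difference of -0.997 (camera, adjusted p = 3e-05; adjusted p = 0.788 with an estimated correlation). Cholesterol synthesis (median -0.89, adjusted p = 0.00012) and fatty acid synthesis (-0.47, 0.0236) were lower in camera (adjusted p = 0.788 with an estimated correlation for both). The cholesterol median was -0.46 in run 1 and -1.10 in run 2. By resampling wells, with 2 CPM added before the logarithm, it was -0.26 (95% interval -0.85 to 0.33) and -1.08 (95% interval -1.41 to -0.82). AT1 markers (median 1.27, adjusted p = 0.00181), the transitional alveolar state (1.33, 0.00851) and G2 and M phase genes (1.94, 0.0236) were higher. These had an adjusted p = 0.788 with an estimated correlation, and G2 and M phase genes 0.885. In run 1 and run 2 their medians were 2.08 and 0.38 for AT1 markers, 1.79 and 0.84 for the transitional state and 2.81 and 1.16 for G2 and M phase genes, larger in run 1 with its 22 wild type wells. Fatty acid synthesis had -0.18 and -0.70. By resampling wells, with 2 CPM added, the G2 and M phase medians were 0.50 (95% interval 0.00 to 1.02) and 0.64 (95% interval 0.09 to 1.48). Their size and their order between runs thus depend on the scale. RAS MAPK output (camera, adjusted p = 0.152), S phase (0.997), ciliated (0.997) and B cell genes (0.584) did not pass.

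In these wells Lyz1, a lysozyme gene of AT2 cells, stood at 2506 and 2631 CPM in wild type runs and 288 and 900 CPM in mutant runs. Ifi27l2a stood at 392 and 1592 CPM in wild type runs and 49.9 and 108 CPM in mutant runs, and Retnla at 49.7 and 27.2 CPM in wild type runs and 475 and 306 CPM in mutant runs. edgeR called 0 of 14740 genes, with 362 at an unadjusted p under 0.05. Adjusted over the list alone, 1 gene each passed in edgeR's test for mesothelial markers (Msln, adjusted p = 0.0153, the only member tested), neutrophil markers (Retnlg, 0.0136) and NF-kB targets (Ccl20, 0.0284). Msln and Ccl20 were among the leading genes of the unnamed cluster of 55 passing wells given above, held mostly by mutant run 1. Without wild type replicate 2, which leaves the 22 wells of run 1 as the wild type, the interferon list did not pass (camera, adjusted p = 0.0876) and edgeR called 223 genes. In the AT2-like cluster of all passing wells, which holds only 7 wells of wild type run 1, the interferon list did not pass and its median was 0.64, though the test pointed downward (camera, adjusted p = 0.383).

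Whether interferon-induced genes differed in many wells or in a few was measured after each deep well was thinned to 50000 reads. Stat2 was detected in 34.5% and 26.9% of wild type wells and in 18.1% and 16.7% of mutant wells. Usp18, a brake on interferon signalling, was detected in 15.5% and 14.2% against 2.5% and 8.81%, and Isg15, a ubiquitin-like modifier, in 13.8% and 9.64% against 5.62% and 5.73%. Among surfactant-high wells alone Stat2 was detected in 31.8% and 29% against 10.4% and 17.1%, while Usp18, at 4.55% and 14.2% against 0% and 7.83%, overlapped between genotypes. Over all deep wells, of the 42 genes of the list, 11 were detected in a lower share of wells in both mutant runs than in both wild type runs. That number was 26 at 25000 reads, 15 at 100000, 10 without thinning over passing wells, and 12 at 50000 among surfactant-high wells. In exchangeable samples 33.3% of genes would separate the genotypes, split evenly over both directions. The 11 count only the lower direction, so they cannot be set against the full 33.3%, though part of the 11 may be chance. Stat2, Usp18 and Isg15 are among the 11, and some other members had a higher mean share in mutant samples. The mean share over the list was 19.8% ± 6.49 in wild type and 14.9% ± 2.48 in mutant samples (SD, n = 2; exact permutation test, two-sided p = 0.667). By run it was 15.2% in wild type and 13.2% in mutant wells of run 1, and 24.4% and 16.7% in run 2, which this test does not pair. At 25000 reads the mean share was 17.8% ± 3.69 and 12.8% ± 1.18 (exact permutation p = 0.333). Without thinning the means over passing wells were 21.4% ± 6.32 and 18.1% ± 2.53.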

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

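The tests within clusters of deep wells were chosen after the data had been seen, while the tests of which wells held the G2 and M phase reads were set before their results were seen. Of 26 lists, 2 had a difference between genotypes that differed between the 2 surfactant-high clusters, and the other 24 did not pass. AT1 markers had a median log2 difference of -0.15 in the AT2-like cluster 3 and 2.71 in cluster 2, which the AT1 gene Ager helps to define (camera on the interaction term, adjusted p = 0.000168; adjusted p = 0.955 with an estimated correlation). G2 and M phase genes had 0.25 and 2.82 over the 15 genes kept in this joint fit (adjusted p = 0.00953; adjusted p = 0.955 with an estimated correlation). Their sign in cluster 3 is not settled, since over the 8 genes kept when that cluster was fitted alone the median was -0.40. edgeR called 0 of 14720 genes for the interaction, with 143 at an unadjusted p under 0.05. Wild type run 1 gave 17 wells to cluster 3 and 5 to cluster 2.

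The reads of the G2 and M phase list, higher in mutant samples, came mostly from a few wells: the 5 richest held 75.2% of them or more in each mutant run, but also 71.1% in wild type run 1. No fit was set up to leave these wells out. The surfactant-high set held 0 of the 5 in mutant run 1 but 4 of them in mutant run 2. The list was still higher there (camera, adjusted p = 0.0236; adjusted p = 0.885 with an estimated correlation). Wells with at least 2 reads of each of at least 5 list genes numbered 1 and 0 in the wild type runs and 19 and 6 in the mutant runs, of which 1 and 5 were surfactant-high. Cells of another type may hold part of the signal, since 94.5% of the list's reads lay outside surfactant-high wells in mutant run 1 and 43.3% in mutant run 2, against 89% and 19% in the wild type runs. The bound set beforehand for such cells was over 50% in each mutant run and the bound against them under 25%, so by these bounds the source cannot be told apart from cycling AT2 cells. The bounds do not weigh where the reads of all genes lay. Surfactant-high wells held 30142053 of 54711511 reads in mutant run 1 and 32704263 of 34828266 in mutant run 2. In the wild type runs they held 19400957 of 37356595 and 37964850 of 43348558. In each sample the list's reads thus lay outside these wells more often than reads of all genes. A rise in cycling AT2 cells with the Kras genotype remains open. By resampling wells the median of the list was 0.50 (95% interval 0.00 to 1.02) in run 1 and 0.64 (95% interval 0.09 to 1.48) in run 2 among surfactant-high wells. In the AT2-like cluster it was 0.00 (95% interval 0.00 to 0.08) and 0.10 (95% interval 0.00 to 0.32). On this scale a gene with no read in both samples of a run gives 0. The median and bounds at 0.00 thus reflect unread genes and do not show that the list was unchanged there.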

How the results depend on the processing

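Deep wells, surfactant-high wells, their clusters and the block within AT2-like clusters were chosen after seeing the data, and the other alternatives before. edgeR's count of 0 genes became 41 with no low-count filter, 67 with DESeq2 and 6 in AT2-like clusters with the replicate block (Lyz1, Retnla, Apoe, mt-Rnr2, Mt1 and 1 unnamed). Leaving out 1 sample gave 0 to 50 genes, and in surfactant-high wells 0, 223, 8 and 45. The replicate block called 0 genes over passing wells and changed no other call there, with the same 9 lists.

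Against 9 lists in the reported fit, 3 lists passed in AT2-like clusters only (2 of the 9), 4 with the block there (3), 5 in thinned wells (5), 1 in the deep AT2-like cluster (1), and 0 with an estimated correlation or with fry. Leaving out wild type 1, wild type 2, mutant 1 and mutant 2 gave 12, 6, 11 and 6 lists, of which 5, 4, 6 and 3 were among the 9. In surfactant-high wells it gave 1, 3, 8 and 5, of which 1, 2, 4 and 2 were. Over the 14 alternatives fixed before the data were seen, with camera, the interferon, cholesterol and G2 and M phase lists each passed in 13, with adjusted p up to 0.383, 0.0778 and 0.709. Ciliated and AT1 lists passed in 10, B cell and transitional lists in 9, and RAS MAPK output and S phase in 8. Directions turned for B cell markers without wild type replicate 2 (-1.90, against 5.98 without wild type replicate 1), and in the deep AT2-like cluster for AT1 markers (-0.14) and G2 and M phase genes (-0.40 over the 8 genes kept there). In the other surfactant-high cluster they turned for ciliated (0.0222) and S phase genes (median 1.91, test downward). In surfactant-high wells ciliated markers turned without wild type replicate 1 (median -0.25, test upward) and without mutant replicate 2 (1.20), and S phase genes without mutant replicate 2 (median 0.25, test downward).

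The Kras log2 difference was -0.91 in AT2-like clusters (-0.83 with the block), 1.08 and -0.76 in the deep clusters, and -0.40 to 0.45 without 1 sample. Shares stayed within 1 SD, though the AT2-like difference ran from -16.6 to 49 points without 1 sample. Without 1 sample that outcome was fixed in advance, since in a group of 2 the mean then moves by less than the SD. Of 3158 values for 140 named genes, 638 moved by over 1 standard error and 218 had the other sign. For all of these the cause was not tested. Alternatives for 1 sample per genotype were not run, as each run was mapped.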

Other observations

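The fit in thinned wells was fixed before the data were examined, but its use on the question of depth and the other tests below were chosen after their results had been seen. Some genes outside the lists that passed stood apart as values, without passing edgeR's test. Nlrc5, the transactivator of MHC class I genes, stood at 60.7 ± 2.63 CPM in wild type and 28.1 ± 6.69 CPM in mutant samples (SD, n = 2), while Psmb10, an immunoproteasome subunit gene, stood at 91.7 ± 7 against 126 ± 18.4 CPM. H2-Ab1, an MHC class II gene, stood at 3801 ± 184 against 2893 ± 633 CPM. Among growth and chemokine genes, Itga2, an integrin gene of the early tumour list, stood at 0.038 ± 0.0537 against 11.4 ± 11.8 CPM, the glycolytic enolase gene Eno1 at 23.1 ± 6.1 against 59.2 ± 9.5 CPM, the chemokine gene Cxcl1 at 5.97 ± 3.05 against 19.3 ± 5.47 CPM and the macrophage growth factor gene Csf1 at 14.3 ± 5.58 against 2.31 ± 1.69 CPM. Reads of 4 Y-linked genes reached 10 or more in 30 of 227 deep wells of mutant run 2 and in 0 deep wells of the other 3 samples. Reads of Xist, the X-inactivation RNA, reached 10 or more in 54 deep wells of mutant run 2, 3 of them among the Y-linked wells, and in 57 of mutant run 1, so the 2 mutant runs differed in the sex markers of their cells.

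Wells with under 20000 reads resembled the deep wells of their own chip column. Their profile correlated across genes with that of their own column at a median r of 0.753 and 0.336 in the wild type runs and 0.513 and 0.145 in the mutant runs, and their own column was the closest in 39 of 39 columns. Within each sample every own-column r lay above every other-column r by at least 0.0496. Each gene was centred over the columns of a sample before correlating, which removes whatever all columns share. RNA free in the cell suspension would reach all columns alike, so this comparison cannot tell whether the wells held such RNA. Reads given to the wrong well of a column stay open: of genes with at least 50% of their reads in 1 well, 21.4% and 17.8% of the remaining reads lay in the same column in the wild type runs and 15.4% and 6.15% in the mutant runs, where chance gives 9.77%, so mutant run 2, with 2 such genes, lay below chance. A stricter minimum of 80%, tried after the value at 50% had been seen, gave 40.6% in wild type run 1, where the share in the same chip row also reached 13.9% against 2.26% by chance, 45.8% in mutant run 1, 72.7% from 1 gene in mutant run 2, and no gene in wild type run 2.

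The type I interferon list was lower in mutant samples. In deep wells thinned to 50000 reads its median log2 difference was -0.64 (camera, adjusted p = 0.000149, and 0.947 with an estimated correlation). Thinning gives each well the same weight but keeps each gene's expected share of a well's reads, and it left out the shallower wells. It thus cannot decide whether depth per well contributes. Cells of another type could contribute: in surfactant-high wells alone the median was -0.91 (95% interval -1.80 to 0.39) in run 1, with an upper bound of 0.386 over 22 wild type wells, and -0.64 (95% interval -1.11 to -0.27) in run 2. Another mix of the 2 surfactant-high clusters stays open too: within the AT2-like cluster the median was -0.01 (95% interval -0.25 to 0.10) in run 1 and -0.31 (95% interval -0.93 to 0.07) in run 2, and within the other cluster -1.33 (95% interval -2.53 to 1.03) and -0.48 (95% interval -1.10 to -0.10). Both intervals of the AT2-like cluster include 0, and although its median was -0.53 on the scale of the report when fitted alone, it did not pass there (camera, adjusted p = 0.112). A lower interferon response in AT2 cells with the oncogenic Kras allele is a hypothesis that these samples cannot settle.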
